A study of Homo sapiens with 6 samples.

How the data were processed

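Gene expression was measured in MV4;11 cells, an established human leukemia cell line with a rearranged MLL gene (KMT2A), on 6 Affymetrix arrays labelled from the 3-prime ends of transcripts. The cells had received either 4 µM MI-389, described in the labels as an inhibitor of the interaction of menin with MLL, or the solvent DMSO, for 6 days, with 0.25% DMSO in both and a change of medium on day 3. Each group held 3 arrays. The labels call the samples biological replicates and do not say how the cultures were separated, so the p-values measure the spread between these samples, which may be partly technical.

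The values were used as deposited, on the log2 scale, 1 per probe set and array. Per the submitters' processing notes, RMA and limma were used, with no versions; their settings, such as the background correction and the set of arrays normalised together, are not given in the sources used here. The deposited log2 values had array medians between 4.47 and 4.49, as after normalisation between arrays. RMA values of dim probe sets are compressed towards a floor, so folds of dim genes are understated. There were no detection calls in the table used. As a guide to background, the 23 control probe sets of nonspecific sequence had values on single arrays from 2.79 to 7.87. These were at most 5.49 when the probe set with the highest GC content was left out. Of the 18239 genes tested, 9571 had a mean below 5.49. No sequencing depth applies to arrays, and the number of arrays limits the precision.

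The table held 49386 probe sets, of which 93 control probe sets were left out of the tests and used as controls of the hybridisation, the labelling and the RNA. Gene names came from the platform annotation, with symbols updated through Entrez gene IDs in the RefSeq gene table of GRCh38.p14. No coordinates were used. Of the 49293 tested probe sets, 45253 were annotated to 1 gene, 1327 to several and 2713 to none in that annotation. The gene ID of 45172 of the one-gene probe sets was found in the RefSeq table, and the other 81 kept the platform's symbol. Each of the 18239 genes was represented by the probe set with the highest mean log2 value over all 6 arrays, among probe sets annotated to that gene alone.

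MI-389 was compared with DMSO using limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, no covariates), with Benjamini-Hochberg adjustment over all probe sets or all genes and a threshold of 0.05 on the adjusted p. Fold changes are differences of log2 means, MI-389 minus DMSO, with the standard error (SE) from limma. "Rose" and "fell" refer to genes past this threshold. Gene groups were 28 lists fixed before the data were examined. They were tested with limma's camera against all other genes, with its preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move on balance one way. Of 563 list members, 517 were measured. The list of the HOXA cluster had 1 measured member, fewer than the minimum of 3, so 27 lists were tested and the camera p-values were adjusted over these 27.

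Genes named in the text follow a rule fixed before the data were examined. It takes the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose groups do not overlap, 20 fixed genes of the menin, MLL and myeloid literature, and up to 3 rising and 3 falling members of each list with the largest changes. Of the 20 fixed genes, 17 had a value and the other 3 were not analysed here. The few genes named outside this rule are said to be so.

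Alternatives fixed beforehand were a shift of each array to a common median, a further quantile normalisation, leaving out genes below the 40th percentile of mean expression, the replicate number as a block, an intensity trend with robust variance estimation, array weights, leaving out each array in turn, the mean of all probe sets of a gene, a preference for probe sets without the suffixes that mark unspecific or shared sequences, a threshold of 0.01, and limma's treat against a fold of 1.2. The suffixes set last were _x_at, _s_at and _a_at, called unspecific below, although _a_at marks sequence shared by transcripts of the same gene. When an array was left out, each gene kept its representing probe set, a decision taken after a first run in which it was chosen anew. Centring the arrays on the hybridisation spike-ins was added after these controls were seen to differ between the groups. The labels do not say that equal replicate numbers share a day or batch.

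The gene test was checked on data simulated for the same comparison with 18239 genes. It recovered 32% of 50 genes changed by 0.25 on the log2 scale, 86% at 0.5, 98% at 1 and 100% at 2, with 4 false calls among 18039 unchanged genes. A simulated list of 30 genes shifted by 0.3 was called, and 0 of 20 unshifted lists were called by camera. The simulated genes were drawn independently, so false list calls through correlated members could not show. Far fewer genes changed than in the data, where 34.1% were called, so the recovery there may differ.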

Results

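MV4;11 leukemia cells were profiled after 6 days with 4 µM MI-389 or with DMSO alone, 3 arrays each. The comparison asks which transcripts change when the interaction of menin with MLL is inhibited in an MLL leukemia line. The arrays of a group correlated at r = 0.997 to 0.998 over all probe sets, and arrays of different groups at 0.979 to 0.981, both across genes, which are not independent replicates. The SD of the log2 differences between arrays was 0.122 to 0.167 within groups and 0.425 to 0.443 between them. The first principal component held 86.4% of the variance and separated the treatments, and the second held 4.91%, with MI-389 replicate 3 apart from the other arrays.

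Monocyte and macrophage markers rose with MI-389 and genes of the ATF4 response fell, as given by list below. The largest measured rise was that of MNDA, a nuclear antigen of myeloid cells, from 3.66 ± 0.06 to 9.67 ± 0.04 (log2 mean ± SD, n = 3 each). GASK1B rose by 5.75 on the log2 scale, the alarmin genes S100A9 and S100A8 by 5.48 each, CYBB, the catalytic subunit of the phagocyte NADPH oxidase, by 5.20, and the scavenger receptor CD36 by 4.20. CACNA2D3, CES1, ANXA1 and GPR183 completed the 10 largest measured rises, at 4.99, 4.83, 4.70 and 4.21. The largest measured fall was that of CBS, the first enzyme of transsulfuration, from 9.89 ± 0.05 to 4.13 ± 0.16. OCSTAMP, a membrane protein of osteoclast fusion, changed by -5.67, the transcription factors MEF2C and DLX2 by -5.21 each, and the branched-chain aminotransferase BCAT1 by -4.23. DDIT4, FCER2, TRIB3, PRDM8 and SDC2 completed the 10 largest measured falls, at -4.47, -4.24, -4.17, -4.07 and -4.00. For these 20 genes the SE was at most 0.153. That the 3 arrays of one group lay above the 3 of the other was a condition of their choice.

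In 9 of the 10 rises and 8 of the 10 falls, the dimmer group lay under 5.49, the highest level of the nonspecific probe sets with the highest GC content left out, so the order of these changes is not settled. Set against that level in place of the dimmer group, MNDA was at least 18.2-fold higher with MI-389, S100A8 at least 28.5-fold, S100A9 at least 9.03-fold, CYBB at least 15.0-fold and CD36 at least 10.3-fold. MEF2C was at least 32.7-fold lower, CBS at least 21.2-fold, DLX2 at least 14.7-fold and OCSTAMP at least 14.4-fold. ANXA1, BCAT1 and TRIB3 had both groups above it. With the mean of all probe sets per gene 7 of the 20 changes moved by over 1.5 times: GASK1B to 2.96, CYBB to 2.46, CACNA2D3 to 2.50, CBS to -3.43, DLX2 to -1.76, BCAT1 to -1.54 and PRDM8 to -1.55. With probe sets without unspecific suffixes preferred, CYBB stood at 3.16, and ANXA1 at 0.0042 and not called. Of their single probe sets, 4 of 4 for CYBB and 4 of 5 for ANXA1 were called higher. For CACNA2D3 1 of 2 was called higher, and for DLX2 1 of 3 lower.

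In all, 6214 of 18239 genes (34.1%) changed at an adjusted p under 0.05, 3352 higher and 2862 lower with MI-389, and 705 of them changed at least 2-fold, 378 higher and 327 lower. At the level of probe sets, 13800 of 49293 changed, 6877 higher and 6923 lower. The groups did not overlap for 8269 genes (45.3%), where chance gives 10%. The balance of higher and lower genes moved little with the rescalings fixed beforehand. Of the changed genes, 49.8% were higher with a common median and 53.8% after a further quantile normalisation. Centring on the hybridisation spike-ins moved it far more. The hybridisation spike-ins, bacterial and phage transcripts added in known amounts, were 0.25 higher (SE 0.04) on the MI-389 arrays. With the arrays centred on them, 12453 genes changed, 1397 higher and 11056 lower, so that 11.2% of the changed genes were higher against 53.9% in the values as deposited, and the median of all genes moved from 0.018 to -0.23. The nonspecific probe sets with a GC content of 3 to 19 differed by 0.0064 (SE 0.02) and those of 20 to 25 by 0.18 (SE 0.05). The offset of the spike-ins was thus not common to all probe sets. Whether it reflects an amount of messenger RNA was not tested. The changes below are those of the values as deposited. The centring lowers the difference of every gene by the same 0.25, and camera compares a list with the other genes. A camera call under the centring is therefore no further support for a list. Against a fold of 1.2 (limma treat), 2457 genes passed, 1282 higher and 1175 lower.

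MEN1, which encodes menin, had a log2 level of 7.16 ± 0.03 with DMSO and 7.10 ± 0.05 with MI-389, a change of -0.06 (95% interval -0.18 to 0.06, adjusted p = 0.467). AFF1, a common fusion partner of MLL, differed by 0.07 (interval -0.06 to 0.20, adjusted p = 0.418). KMT2A, which encodes MLL, rose by 0.51 (SE 0.07, adjusted p = 1.7e-04). Whether these probe sets read a fusion transcript, the intact genes or both was not checked, as no coordinates were used. The gene MEN1 changed by -0.31 with the spike-in centring (limma adjusted p = 0.0024), which lowers every gene alike and so says nothing of MEN1 itself. Among 18 genes of the menin and MLL complexes, 5 rose and 2 fell, the latter CDK9 (-0.55) and MLLT10 (-0.51), and camera did not call the list (median -0.01, mean 0.01, adjusted p = 0.990). The counts adjusted over the list alone were also 5 and 2, and with the arrays centred on the spike-ins they turned to 1 higher and 10 lower (median -0.26), again not called by camera but called lower by fry (adjusted p = 0.0154).

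Of 23 measured target genes of MLL fusions, 15 fell and 0 rose, 17 and 0 when adjusted over the list alone, with a median log2 change of -0.71 (camera adjusted p = 1.25e-11 with the preset correlation, and 0.0987, not called, with an estimated correlation). Fry called the list lower (adjusted p = 3.8e-05). The median was -0.43 with the mean of all probe sets per gene and -1.22 with dim genes left out, called lower in both by camera with the preset correlation. MEIS1, a homeobox cofactor of leukemic self-renewal, went from 8.18 ± 0.08 to 4.47 ± 0.14, at least 6.47-fold lower when set against 5.49. PBX3, its partner, was 4.17-fold lower, BCL2, an inhibitor of apoptosis, 3.72-fold, the receptor tyrosine kinase FLT3 2.67-fold and CDK6, a kinase of the G1 phase, 2.03-fold. The list was composed from general knowledge of MLL leukemia and not chosen on these samples. HOXA2, the measured member of the HOXA cluster, had a log2 level of 3.70 ± 0.04 with DMSO, in the range of the nonspecific probe sets, and a change of 0.02 (adjusted p = 0.837). The other HOXA genes were not analysed here. In the HOXB cluster, 7 of 10 measured genes had means under 5. HOXB7 (-0.41, with both groups under 5.49) and HOXB3 (-0.28) fell, 0 rose, both counts the same when adjusted over the list alone. Camera did not call this list (adjusted p = 0.435), and fry called it lower (adjusted p = 0.00504). The counts were 0 higher and 8 lower when the arrays were centred on the spike-ins.

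**Figure D1:**
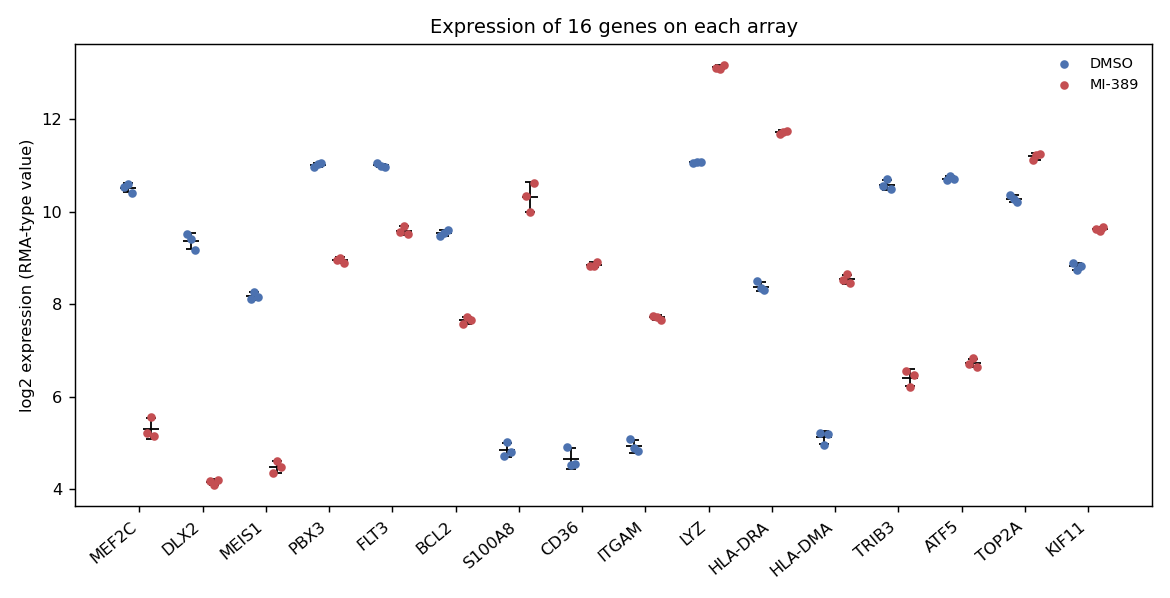
Expression of 16 genes on the 6 arrays, as log2 values. Points are single arrays (blue DMSO, red MI-389), the horizontal mark is the mean and the bars are ± 1 SD, n = 3. For MEIS1 the DMSO mean was 8.18 and the MI-389 mean 4.47, and for S100A8 the order was the other way, 4.84 and 10.3.

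Monocyte and macrophage markers rose: 25 of 36 were higher and 2 lower, with the same counts adjusted over the list alone, and a median change of 0.64 (camera adjusted p = 3.89e-11, and 0.0174 with an estimated correlation). The median was 1.09 with dim genes left out, still called higher. With the spike-in centring it was 0.39, and camera called the list higher than the other genes, which are lowered alike. ITGAM, the integrin alpha chain CD11b, rose from 4.93 ± 0.14 to 7.71 ± 0.05, at least 4.68-fold when set against 5.49, lysozyme (LYZ) 4.18-fold to 13.1 ± 0.04, and the M-CSF receptor CSF1R 3.15-fold. CD14 rose by 0.72, but its log2 levels of 3.59 and 4.30 lay in the range of the nonspecific probe sets. The 2 members that fell were FCGR1A (-1.27), a receptor for immunoglobulin G, and the transcription factor CEBPB (-0.27). Of 24 neutrophil and granule genes, 9 rose and 1 fell, the same over the list alone. This list had a median of 0.14 (camera adjusted p = 0.0016, and 0.127 with an estimated correlation), and of 0.44 with dim genes left out. With the spike-in centring its median was -0.11, with 6 members higher and 7 lower, and camera still called it higher than the other genes (adjusted p = 3.9e-05). The granule protease genes PRTN3 and ELANE rose 4.97-fold and 3.89-fold, RNASE2 rose 4.41-fold, and S100P fell, at least 1.25-fold when set against 5.49. MPO changed by 0.25 (SE 0.06) with both groups under 5.49, and by -0.0025 with the spike-in centring. Of 24 stem and progenitor genes 3 were higher and 5 lower, the same over the list alone, and camera did not call the list (median -0.01, adjusted p = 0.476). These counts became 1 and 14 when the arrays were centred on the spike-ins (median -0.27), where fry called the list lower (adjusted p = 0.0086) and camera did not. KIT, the stem cell factor receptor, went from 5.58 ± 0.22 to 4.46 ± 0.17, at least 1.07-fold lower when set against 5.49, with 1 of its 3 probe sets called. ITGA6 fell by 0.91, and CD47 rose by 0.76.

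Genes of MHC class II antigen presentation rose in 8 of 11 cases, with 0 lower, also over the list alone, and a median change of 1.91 (camera adjusted p = 5.7e-07, and 0.0350 with an estimated correlation). With unspecific suffixes last the median was 0.51, still called. HLA-DMA rose by 3.43 on the log2 scale, at least 8.33-fold when set against 5.49, HLA-DPA1 10.7-fold and HLA-DRA 10.1-fold, the last from 8.38 ± 0.10 to 11.7 ± 0.04. The gene HLA-DRA had 2 of 3 probe sets higher, and with a probe set without an unspecific suffix preferred its change was 0.032 and not called. CIITA, the transactivator of these genes and a member chosen for mention after its value was seen, changed by 0.13 with both groups under 5.49 (adjusted p = 0.543). Lysosome genes rose in 18 of 26 cases and fell in 2, 20 and 2 over the list alone, with a median of 0.59 (camera adjusted p = 1.78e-07, and 0.0314 with an estimated correlation). The median was 0.25 with unspecific suffixes last, still called higher. With the spike-in centring it was 0.33, and camera called the list higher than the other genes, which are lowered alike. Progranulin (GRN) rose 3.90-fold and prosaposin (PSAP) 3.90-fold, while ATP6V1H (-0.36), a subunit of the proton pump, and the ion channel MCOLN1 (-0.33) fell. Of 18 cholesterol synthesis genes 10 rose and 0 fell, also over the list alone, with a median of 0.28 (camera adjusted p = 0.00266, and 0.371 with an estimated correlation). CYP51A1 rose by 0.69 and SC5D by 0.66. With the spike-in centring this list had 5 members higher and 6 lower and a median of 0.030, and camera still called it higher than the other genes (adjusted p = 0.0016).

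**Figure D2:**
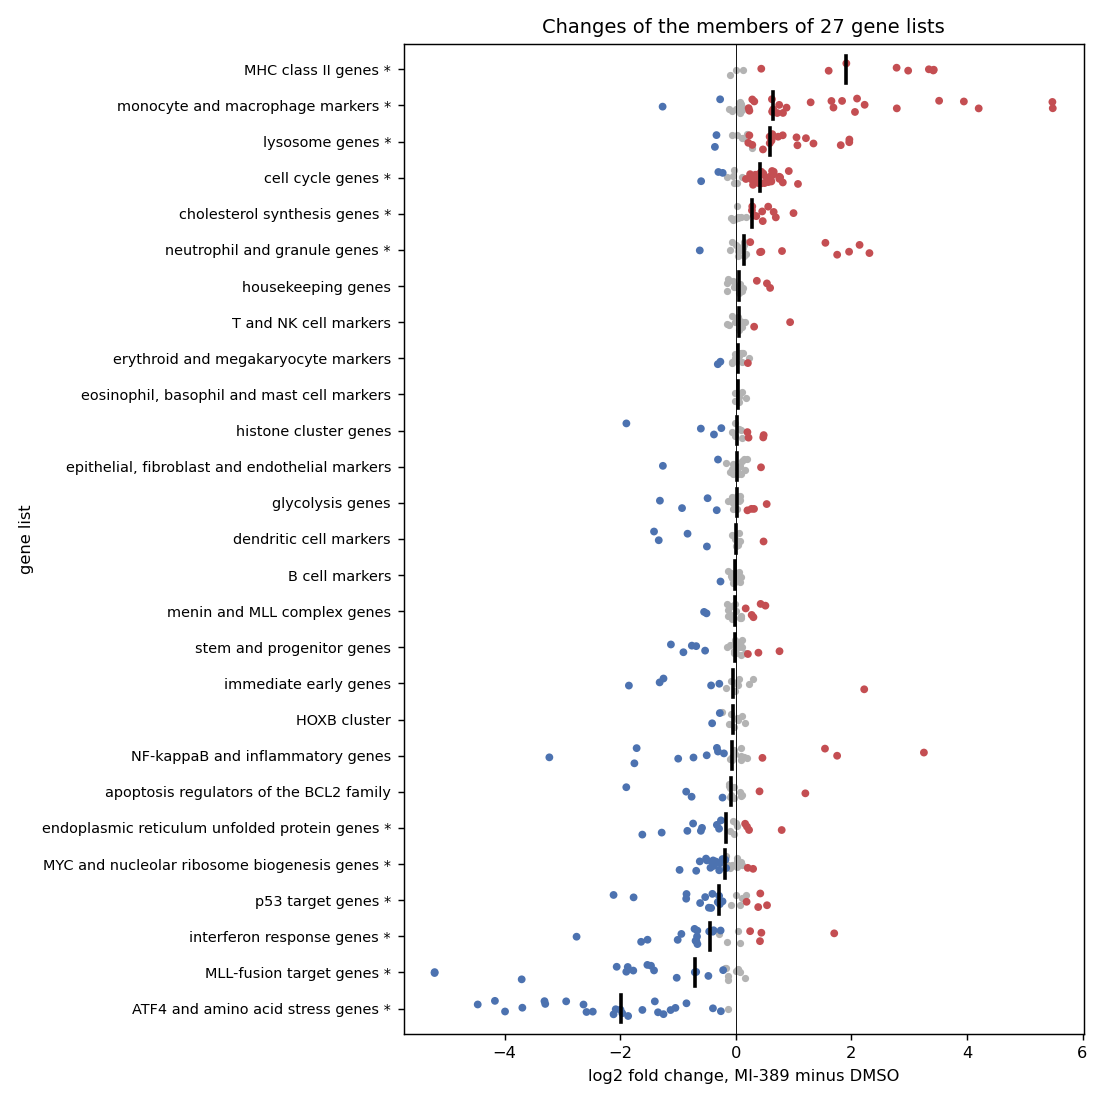
Log2 fold changes, MI-389 minus DMSO, of the measured members of 27 gene lists, 1 row per list. Each point is a gene, red if higher and blue if lower at an adjusted p under 0.05 and grey otherwise, black bars are list medians, and a star marks a camera adjusted p under 0.05 with the preset correlation, a call that 7 of the 12 starred lists lose with an estimated correlation. Medians run from -1.995 for the ATF4 list to 1.91 for MHC class II genes. With the arrays centred on the spike-ins the median of the neutrophil and granule list is -0.11 instead of 0.14. Camera with the preset correlation still calls this list higher than the other genes, which that centring lowers alike. With the estimated correlation the list is not called on the values as deposited (camera adjusted p = 0.127).

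Genes of the ATF4 response, which supplies amino acids and answers their shortage, fell in 24 of 25 cases, with 0 higher, also over the list alone. Their median change was -1.995 (camera adjusted p = 1.76e-26, and 0.0148 with an estimated correlation), the lowest of the 27 lists. TRIB3, a pseudokinase induced by ATF4, went from 10.6 ± 0.11 to 6.41 ± 0.18, a log2 change of -4.17. DDIT4, an inhibitor of mTORC1 signalling, was at least 16.1-fold lower when set against 5.49, the transcription factor ATF5 15.9-fold and the leucine sensor SESN2 4.33-fold. ATF4 itself, a member chosen for mention after its value was seen, was lower by -1.40 (SE 0.06). Genes of the unfolded protein response of the endoplasmic reticulum counted 4 of 18 higher and 9 lower, the same over the list alone, and a median of -0.18 (camera adjusted p = 0.00696, and 0.0987 with an estimated correlation). This list had a median of -0.43, with 1 member higher and 14 lower, when the arrays were centred on the spike-ins. XBP1 (-1.62), DNAJB9 (-1.28) and HERPUD1 (-0.84) fell, and the chaperone CALR rose, at least 1.59-fold when set against 5.49. Of 22 p53 target genes 4 rose and 13 fell, the same over the list alone, with a median of -0.28 (camera adjusted p = 0.00416, and 0.0987 with an estimated correlation). The list's median was -0.54, with 1 member higher and 16 lower, when the arrays were centred on the spike-ins. SESN2, which is also in the ATF4 list, the cyclin kinase inhibitor CDKN1A (-1.77) and BBC3 (-0.86) fell, and DDB2 (0.42) and SESN1 (0.39) rose. Of 16 BCL2 family genes 2 rose and 4 fell, the same over the list alone, with a median of -0.08. Camera did not call this list (adjusted p = 0.172), and fry called it lower (adjusted p = 0.00125). The counts were 1 higher and 11 lower when the arrays were centred on the spike-ins. BIK rose 2.30-fold, and PMAIP1 fell by 0.76.

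Cell cycle genes rose in 31 of 40 cases and fell in 3, the same over the list alone, with a median of 0.41 (camera adjusted p = 1.86e-08, and 0.0443 with an estimated correlation). The mitotic kinesins KIF20A and KIF11 rose 2.11-fold and 1.76-fold. Topoisomerase TOP2A rose 1.89-fold from 10.3 ± 0.07 to 11.2 ± 0.07. The licensing factor CDT1 (-0.60) and the mitotic kinase PLK1 (-0.30) were among those that fell. With the spike-in centring 18 members were higher and 8 lower, with a median of 0.16. Camera still called the list higher than the other genes, which that centring lowers alike (adjusted p = 4.1e-11). MYC stood at 11.4 ± 0.07 in both groups, with a change of -0.06 (95% interval -0.21 to 0.08, adjusted p = 0.497). The gene MYC changed by -0.32 with the spike-in centring (limma adjusted p = 0.0041), which lowers every gene alike and so says nothing of MYC itself. Of 29 genes of MYC and of nucleolar ribosome biogenesis, 2 rose and 16 fell, 2 and 17 over the list alone, with a median of -0.18 (camera adjusted p = 2.39e-04, and 0.0987 with an estimated correlation). This list had a median of -0.43 when the arrays were centred on the spike-ins. RCL1 (-0.97), PES1 (-0.69) and RRP9 (-0.62) fell, and NOP56 rose by 0.30.

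Interferon response genes fell in 16 of 24 cases and rose in 4, 17 and 4 over the list alone, with a median of -0.44 (camera adjusted p = 7.97e-05, and 0.369 with an estimated correlation). The list's median was -0.70 when the arrays were centred on the spike-ins. IFITM1, a membrane protein that restricts virus entry, was 6.75-fold lower, and OAS2 at least 1.18-fold when set against 5.49. USP18 (-1.64) and HERC5 (1.70) passed the threshold with both groups under 5.49. Of these 24 genes, 14 had means under 5. Of 23 NF-kappaB and inflammatory genes 4 were higher and 9 lower, and camera did not call the list (median -0.06, adjusted p = 0.372). Set against 5.49, the chemokine gene CXCL8 rose at least 4.53-fold, the chemokine gene CCL2 was at least 3.82-fold lower, and TNF at least 2.47-fold lower. TNFAIP3, an inhibitor of TNF signalling, fell by 1.72 on the log2 scale. Among 14 immediate early genes JUN alone rose, at least 2.20-fold when set against 5.49, and 5 fell, among them EGR1 (-1.85) and JUND (-1.32), and neither camera (median -0.05, adjusted p = 0.263) nor fry called the list. Of 19 glycolysis genes 4 rose and 4 fell (median 0.02, mean -0.10, camera adjusted p = 0.476), with PDK1 (-1.31) and PFKP (-0.49) lower and ALDOC (0.53) higher. Of 14 histone genes 4 rose and 4 fell (median 0.02, mean -0.11, camera adjusted p = 0.677), with H2BC12 at -1.89. Of 13 housekeeping genes 3 rose and 0 fell (median 0.06, camera adjusted p = 0.476), among them GUSB (0.54) and B2M (0.36). In these 5 lists the counts over the list alone were the same, except that 2 immediate early genes rose. Fry called the NF-kappaB (adjusted p = 0.0384), glycolysis (0.0179) and histone (0.0113) lists lower and the housekeeping list higher (0.00502). The balance in these 5 lists depended on the scaling. Centred on the spike-ins, 1 glycolysis gene was higher and 13 lower (median -0.24), 2 histone genes were higher and 8 lower, and 4 NF-kappaB and inflammatory genes were higher and 14 lower. JUN stayed the immediate early gene that was higher, beside 11 lower, and fry called that list lower (adjusted p = 0.0078). Of the housekeeping genes 2 were higher and 8 lower (median -0.20), and fry, a test against no change, no longer called them (direction down, adjusted p = 0.0655). Camera called none of these 5 lists there.

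Markers of other cell types mostly lay near background, and camera called none of these 6 lists on the values as deposited with all genes. Fry called the T and NK cell markers higher (adjusted p = 0.00467) and the dendritic cell markers lower (adjusted p = 9.8e-04), and the adjusted p values in the next sentences are those of camera. T and NK cell markers had 2 of 15 higher and 0 lower (median 0.05, adjusted p = 0.476), NKG7 at 0.94 and CD3D at 0.32, the latter with both groups under 5.49. B cell markers had 0 of 13 higher and 1 lower (median -0.009, adjusted p = 0.594), CD79A at -0.27 with both groups under 5.49. Erythroid and megakaryocyte markers had 1 of 14 higher and 2 lower (median 0.04, camera direction down, adjusted p = 0.990). Eosinophil, basophil and mast cell markers had 0 of 8 changed in limma at an adjusted p under 0.05 (median 0.04, adjusted p = 0.723). Dendritic cell markers had 1 of 14 higher and 4 lower (median 0.01, mean -0.24, camera direction down, adjusted p = 0.211), among them FLT3 and BATF3, the latter at least 1.77-fold lower when set against 5.49. With dim genes left out this list had a median of -0.67 and camera called it lower (adjusted p = 0.0474). Epithelial, fibroblast and endothelial markers had 1 of 18 higher and 2 lower (median 0.02, mean -0.04, adjusted p = 0.877), with KRT18 at least 1.48-fold lower when set against 5.49. Over the list alone, 0 B cell markers fell, 0 erythroid markers rose and 1 epithelial, fibroblast or endothelial marker fell, and the other counts were the same. With the spike-in centring the medians of these 6 lists lay between -0.26 and -0.21, beside -0.23 for all genes. Fry called all 6 lower there, the T and NK cell list (adjusted p = 0.0376) thus the other way, with 1 of its markers higher and 9 lower, while camera called none.

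Of the 27 lists, 12 were called by camera with the preset correlation, 6 higher and 6 lower, and 5 of these with an estimated correlation: monocyte and macrophage markers, cell cycle genes, MHC class II genes, lysosome genes and ATF4 genes. Fry, which tests against no change, called all 12 in the same direction on the values as deposited. With the spike-in centring fry lost the cholesterol synthesis genes (adjusted p = 0.653). Control probe sets for 28S ribosomal RNA were 1.06 higher (SE 0.09) on the MI-389 arrays and those for 18S ribosomal RNA 0.70 (SE 0.14), while the probe sets for poly-A spike-ins, a control of labelling, differed by -0.01 (SE 0.01) at a mean near background of 3.36. The difference of the 3-prime and 5-prime probe sets of ACTB, a measure of RNA integrity, was 1.30 ± 0.08 with DMSO and 1.64 ± 0.23 with MI-389, and that of GAPDH was -0.11 ± 0.02 and 0.037 ± 0.020.

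**Figure D3:**
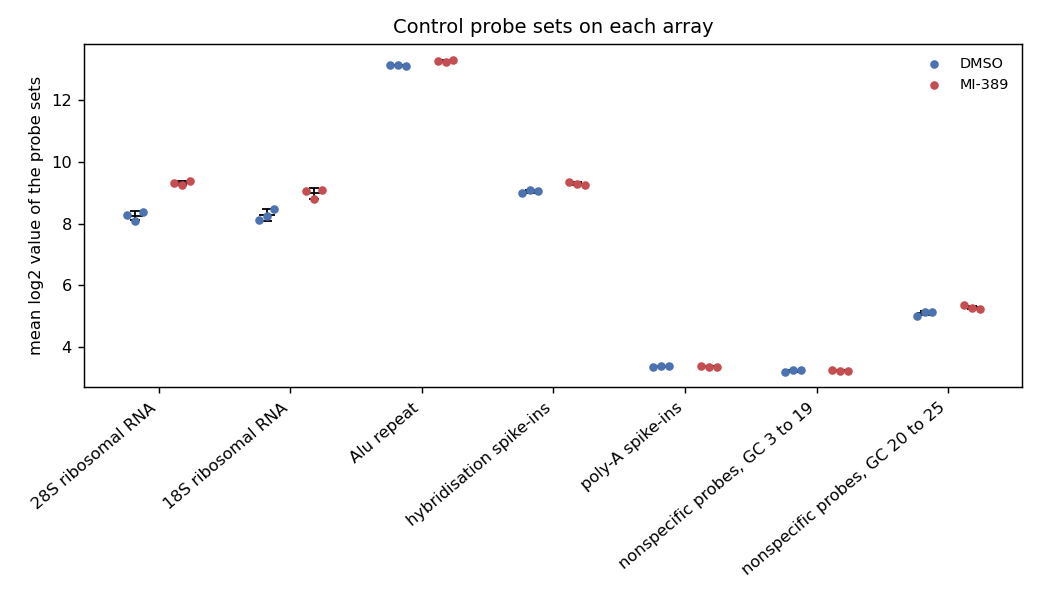
Mean log2 value of 7 families of control probe sets on the 6 arrays. Points are single arrays (blue DMSO, red MI-389), the horizontal mark is the mean and the bars are ± 1 SD, n = 3. The 28S ribosomal RNA probe sets average 8.25 with DMSO and 9.31 with MI-389, and the hybridisation spike-ins 9.05 and 9.30.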

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

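The tests of hybridisation strength and of RNA degradation in this part, and the threshold that picked out these control probe sets (all MI-389 arrays above all DMSO arrays, by more than 2 pooled SD), were chosen after the control values had been seen.

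Outside the gene comparison, 8 measures from control probe sets passed that threshold. Those for 28S ribosomal RNA were higher by 1.06 on the log2 scale (8.25 ± 0.14 against 9.31 ± 0.06), and those for 18S ribosomal RNA by 0.70 (8.28 ± 0.18 against 8.98 ± 0.17). The 5-prime probe set of 28S was higher by 2.10 and the 3-prime probe set of 18S by 1.44. The Alu repeat probe set was higher by 0.15, and the hybridisation spike-ins by 0.25. The nonspecific probe sets with a GC content of 20 to 25 were higher by 0.18, and the difference of the 3-prime and 5-prime probe sets of GAPDH by 0.14.

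The 28S rise less the spike-in rise was 0.81 (SE 0.11). Both rises were known when this comparison was chosen, so it could not decide whether stronger hybridisation caused the 28S difference. The control families also did not share a common shift: nonspecific probe sets with a GC content of 3 to 19 differed by 0.0064, those of 20 to 25 by 0.18. RNA degradation also stays open. The correlation of the 28S value with the 3-prime over 5-prime difference of ACTB averaged 0.65 within groups (0.43 in DMSO and 0.87 in MI-389), and 3 arrays per group are too few to decide. GAPDH was left out of that correlation. Replicate 3 had the highest 28S value in each group. Its GAPDH difference was the highest in DMSO (-0.084) and the lowest in MI-389 (0.015). The 3-prime difference of ACTB itself was 0.34 higher with MI-389 (SE 0.14). Much of this came from MI-389 replicate 3, at 1.91, while replicates 1 and 2 stood at 1.54 and 1.48, beside a DMSO mean of 1.30. A higher content of ribosomal RNA relative to messenger RNA in treated cells is an open explanation that was not tested.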

How the results depend on the processing

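Centring on the spike-ins was chosen after seeing the data; the other alternatives were fixed beforehand, except that keeping each gene's probe set in the fits without 1 array was decided after a first run. Of 83 counts, 74 stayed within 1.5 times the main count, and of 1984 values of the 133 named genes 1886 kept their direction and their side of the threshold, 84 lost the call, 2 gained one and 12 reversed. Of 404 list medians, 2 reversed and 1 gained a call, that of the immediate early genes with unspecific suffixes last. A change of sign where neither fit called the gene or list was not counted as a reversal (1 value of a named gene and 38 list medians). With the spike-in centring 33091 probe sets and 12453 genes changed, 1397 higher and 11056 lower, and 68.5% of the 6214 calls were kept, since that setting lowers the difference of every gene by 0.25. Values between 0 and that shift change sign by its construction, which says nothing of the single genes. They were the median of the neutrophil and granule list (-0.11, with the camera call kept), MPO (-0.0025), CD93 (-0.043), POLR1A (-0.046), CRELD2 (-0.023), HSP90B1 (-0.059), H2BC6 (-0.032) and KLF1 (-0.044), and none of these 7 genes was called there. MEN1 and MYC became called lower through the same shift. Against a fold of 1.2, 5346 probe sets and 2457 genes passed, 1282 higher and 1175 lower, fewer by the construction of that test. Of 130 named genes that were called, 48 moved by over 1.5 times with the mean of all probe sets per gene, 17 with unspecific suffixes last and 46 with the spike-in centring. With the mean of all probe sets per gene, 463 genes changed at least 2-fold and CHEK1 stood at 0.094. With unspecific suffixes last, CRELD2 (-0.030), H2BC5 (-0.78), SDHA (-0.031) and CLEC10A (0.19) reversed, and 9 named genes lost the call, ANXA1 and HLA-DRA among them. The probe sets replaced for CRELD2, H2BC5 and CLEC10A carried the suffix _a_at and were not unspecific by it. With dim genes left out, the dendritic cell list had a median of -0.67 (adjusted p = 0.0474). For these probe set and filter choices the cause was not tested. With an estimated correlation 7 list calls of camera were lost, among them MLL-fusion targets (adjusted p = 0.0987), neutrophil and granule genes (0.127) and MYC and nucleolar genes (0.0987). The estimated correlations of the p53 targets (-0.012) and the unfolded protein genes (-2.4e-04), also lost, lay below the preset 0.01. Correlated members thus do not explain every loss. The monocyte and macrophage list also had an estimated correlation below the preset (-0.019). Its camera adjusted p still went from 3.89e-11 to 0.0174. A weaker call with the estimated correlation therefore does not by itself show correlated members. No list call of camera with the preset correlation was lost with fry on the values as deposited. With fry, 8 further lists were called: HOXB, BCL2 family, NF-kappaB, glycolysis, histone and dendritic cell genes lower, and housekeeping genes and T and NK cell markers higher. Of these calls, those of the 6 lower lists held with the spike-in centring, that of the housekeeping genes was lost and that of the T and NK cell markers turned to lower, since fry tests against no change and that setting lowers every gene. Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.18, 0.026 and -0.11, and with the replicate block 5725 genes changed. Leaving out 1 array gave 5216 (without DMSO replicate 2) to 6160 (without MI-389 replicate 3) changed genes, and all 12 list calls were kept. CD79A, CD93, CEBPB, COL1A1, EPOR, H2BC6, HSP90B1, KLF1, PLK1 and POLR1A lost the call without at least 1 array, with adjusted p up to 0.160. Signal near background limits what can be said of dim genes, as 9571 of the 18239 genes had means below the 5.49 of the nonspecific probe sets.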

Other observations

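The 7 lists in this part and the tests of HLA sequence sharing, of B cells and of an offset between arrays were chosen after the results had been seen. The test of expression level was written after the changes of the cell cycle genes were known but before its own outcome, and that of the transfer RNA synthetases after the fall of CARS1 (-1.995) was known but before its own outcome.

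Toll-like receptors and their adaptors, sensors of microbial products, rose in 6 of 13 cases and fell in 1, with a median of 0.16 (camera adjusted p = 0.0217, and 0.167 with an estimated correlation). TLR4 rose by 2.23 on the log2 scale, and TLR8 rose from a level under 5.49. LY96, the partner of TLR4 in binding endotoxin, was lower by -1.79 with both groups under 5.49. Leukocyte immunoglobulin-like and siglec receptors were split, 7 higher and 3 lower of 13 (median 0.22, camera adjusted p = 0.225), with LILRB2 higher from a level under 5.49 and SIGLEC7 at -0.50. Of 4 measured subunits of the phagocyte NADPH oxidase, CYBB, at least 15.0-fold when set against 5.49, and NCF4 (0.24) rose and RAC2 (-0.42) fell, and camera did not call the list (median 0.17, adjusted p = 0.304). Respiratory chain subunits rose in 14 of 27 cases and fell in 3 (median 0.17, camera adjusted p = 0.0217, and 0.167 with an estimated correlation). Cytosolic ribosomal protein genes had 3 of 29 higher and 0 lower (median 0.033, camera adjusted p = 0.347). Fry called all 5 of these lists higher, among them the receptors of the leukocyte immunoglobulin-like and siglec families (adjusted p = 0.0020), the NADPH oxidase subunits (4.2e-04) and the ribosomal protein genes (0.0051). With the arrays centred on the spike-ins the medians of these 5 lists lay below 0. There fry kept the call for the toll-like receptors and the NADPH oxidase subunits, turned it to lower for the ribosomal protein genes (0 higher and 23 lower, adjusted p = 0.0149), and lost it for the other two, and camera no longer called the respiratory chain subunits (2 higher and 11 lower, adjusted p = 0.0685) and called the leukocyte immunoglobulin-like and siglec receptors higher than the other genes (adjusted p = 0.0449). These genes and lists were chosen after their values were seen.

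The enzymes that load transfer RNAs were also set apart by compartment, as a hypothesis on the fall of ATF4 genes: if it reaches ATF4-driven amino acid supply in the cytosol, cytosolic synthetases, known ATF4 targets in part, may fall and mitochondrial ones not. Of 19 cytosolic synthetases 13 fell and 1 rose (median -0.95, camera adjusted p = 8.72e-11, and 0.167 with an estimated correlation), and of 16 mitochondrial ones 5 rose and 4 fell (median 0.077, camera adjusted p = 0.639). With the arrays centred on the spike-ins, which lowers every gene alike, 0 cytosolic synthetases were higher and 18 lower. Of the mitochondrial ones 2 were higher and 8 lower, with a median of -0.18. Fry called the mitochondrial list lower there (adjusted p = 0.0149), and camera did not call it (adjusted p = 0.645). As deposited its median was not below 0, but 4 members fell, so not falling does not hold for each of them. The mitochondrial list was also dimmer, at a mean log2 level of 7.05 with DMSO against 10.1. The cytosolic and mitochondrial medians differed by -1.03 (two-sided permutation test over genes, p = 0.00026), and genes are not independent replicates. WARS1 (-2.27) and AARS1 (-2.09) had the largest falls, and QARS1 (0.02) and FARSA (-0.04) were not called. A fall of ATF4 activity is a candidate explanation that these data were also used to find, and the protein was not measured.

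Cell cycle genes rose with MI-389, beside falls of MEIS1 and CDK6. A trend with expression level is argued against, since the list median of 0.41 lay above all 10000 random lists matched on mean expression (percentile 100, random median 0.0043). An offset between arrays as the cause of a median above 0 stays open. The spike-in centring left a median of 0.16 (SE of the spike-in shift 0.04), with 18 of 40 members higher and 8 lower, but it lowers every gene by the same amount and so decides nothing on the cell cycle genes themselves. A difference in proliferation or in cell density after the medium change on day 3 was not tested.

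MHC class II genes rose, while CIITA was not called. Cross-hybridisation between similar HLA genes may add to single values, and as the cause of the rise it stays open. The lowest lower 95% bound of CD74, HLA-DMA and HLA-DMB was 1.43. Their rise was known when this test was written, so it could not decide. Whether they share sequence with the other members was not checked on the probes. With unspecific suffixes last the list median was 0.51 in place of 1.91, still called higher by camera. CD74 and HLA-DMB were chosen after their values were seen. The B cell markers did not rise with these genes. Their median was -0.0090, and the highest upper bound among CD79A, CD79B, MS4A1 and PAX5 was 0.21. These values were known when the test of B cells in the cultures was written, so it could not decide. Of the 13 markers, 11 had means under 5. Other explanations, among them a change of the cells with treatment, were not tested.

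Splitting the 6 arrays in the 10 possible ways into 3 and 3 gave 6214 changed genes for the treatment split, as many in 1 of the 10 splits, and at most 0 in limma for any other split (571 at an unadjusted p under 0.05, against 7571 for the treatment split). Splits of 6 arrays are too few for a share under 0.05.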
